A study of Mus musculus with 10 samples.

How the data were processed

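RNA of the secondary palate of mouse embryos at E14.5 was hybridised to an Affymetrix mouse expression array, 1 array per sample, with 5 samples of the Tgfbr2 conditional mutant (floxed Tgfbr2 with Wnt1-Cre) and 5 of the control (floxed Tgfbr2 with no Cre in the genotype label, called wildtype in the titles). The extract protocol in the labels names a column-based kit for total RNA, and the labelling protocol is the standard Affymetrix one. The deposited values are log2 values made by the authors with RMA (background correction, quantile normalization and probe summary), per the submitters' processing notes, which give no version. The values in the table fit the log2 unit: they run from 2.2 to 14.3 and carry 1 decimal, so steps of 0.1 limit small differences and make ties common. Array medians were 6.4 or 6.5. Software, filters and batches are not given in the sources used here. No pair of arrays was a duplicate, the highest share of identical rounded values between 2 arrays being 26.8%. All columns of the table belong to a sample.

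Of 45101 probe sets, 34958 carried 1 gene symbol in the platform annotation, 932 several and 9211 none, and only those with 1 symbol were used for genes. Symbols were looked up through the Entrez gene ID in a RefSeq gene table of another source (assembly GRCm38.p6), in which 34754 of the 34958 were found; that table was used only for names and for the order of neighbouring genes. Each of 18194 genes was represented by its probe set with the highest mean over all 10 arrays. Of the 76 genes named by the rule, 32 had more than 1 probe set, and none of these had a probe set called in the opposite direction. Of the 26 of these that were called, 3 had every probe set called in a test of all probe sets, 19 some, and Cdkn1a, Id4, Tfrc and Laptm5 none.

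Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the log2 values, mutant minus control, two-sided, with no filter and no covariate, and Benjamini-Hochberg adjustment over all genes. A gene counted as changed at an adjusted p under 0.05, and a second count added a fold change of at least 1.5. Errors are the SD over 5 arrays of a group or the standard error (SE) of the fitted log2 fold change, and confidence intervals are at 95%. The comparison, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Genes named are Tgfbr2, Tgfb1, Tgfb2, Tgfb3, Tgfbr1 and Tgfbr3, the 10 largest increases and 10 largest decreases among changed genes whose arrays separate the groups, and from each list up to 3 called members with the smallest p, or the 1 with the smallest p where none was called. Genes with only a clone or predicted-gene name, and sex-linked genes, were passed over in the 10 and 10. Nrros, Smtn, Acta2, Rgs5, Spry1, Notum, Sfrp4, Wnt11, Wnt5b, Erg and Lyve1, which complete counts of 5 or fewer, Dlx1as and Dnaic2, and all genes named in the closing section outside this rule were chosen after their values were seen.

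The 26 gene lists cover TGF-beta signalling and its targets, matrix, skeletal and muscle lineages, proliferation, palatal transcription factors, signalling pathways, metabolism, stress and other cell types; 43 of the 687 genes written in these lists and the sex-linked list had no row of their own and were not analysed here. Lists were tested with limma's camera against all other genes with a preset inter-gene correlation of 0.01, adjusted over the 26 lists, and again with the correlation estimated per list; fry was run beside it and tests whether the genes of a list move on balance in 1 direction. By fry, cell cycle, cholesterol biosynthesis and hypoxia and glycolysis passed (adjusted p = 5.12e-05, 0.00158 and 9.16e-06), and skeletal muscle did not (0.0654). Fry also gives a mixed test, which counts changes in either direction. A list can pass the mixed test when some members change, even if it does not differ from other genes. Counts of called members are given over all genes and adjusted over the list alone. After the data were seen, an exact two-sided permutation test of each array's median deviation over a list was added; the smallest p it can give is 0.00794, and after adjustment over 26 lists none was under 0.0688. Members shared between lists are counted in each.

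The fit and the list test were first tested on simulated arrays made from the real means and residual spreads of the 18194 genes, rounded like the deposited values, with 200 genes changed by known amounts. For this comparison the fit recovered 9 of 50 genes changed 1.2-fold, 40 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 49 of 50 changed 3-fold, and called 10 unchanged genes. The list test recovered the 1 shifted list and called 0 of 25 unshifted lists, whose genes were simulated as independent.

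Alternatives were the mean of all probe sets of a gene, the brighter 60% of genes, an intensity trend with robust fitting, quantile normalization again, centring on array medians, array weights, the replicate number as a block, each array left out in turn, an estimated correlation in camera, limma's treat against a 1.2-fold change, and a test of every probe set. Added after the data were seen were the Eif2s3y value as a covariate, a random value of up to 0.05 added to every deposited value to test the rounding, and the skeletal muscle median as a covariate. Other splits of the 10 arrays into 5 and 5 were tested for each count, 100 of the 126 possible ones drawn with a fixed seed. Figures were drawn with matplotlib 3.10.9.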

Results

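Gene expression was measured in the secondary palate of mouse embryos at embryonic stage E14.5, while the palatal shelves fuse. The mutant group had 5 arrays from embryos in which Wnt1-Cre, a recombinase active in the neural crest, deletes floxed alleles of Tgfbr2, the type II receptor for TGF-beta. The control group had 5 arrays from embryos whose genotype label has the floxed alleles and no Cre, and whose titles say wildtype. The series asks which genes depend on TGF-beta signalling in the neural crest cells that build the palate, whose loss leads to a cleft. The earlier stage that the series design also names was not analysed here. Each array reported 45101 probe sets as log2 values between 2.2 and 14.3, with array medians of 6.4 or 6.5. The number of arrays limits the precision. The labels number the samples but do not say that each came from a separate embryo, so p-values measure the spread between these samples only.

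In mutant palate, more genes fell than rose. Of 18194 genes tested with limma, 1503 changed at an adjusted p under 0.05, of which 975 (64.9%) were lower and 528 (35.1%) higher. Most changes were small: 292 genes changed at least 1.5-fold, 147 upward and 145 downward, so the excess of decreases lay in the smaller changes. Without control replicate 1, 169 genes were higher and 128 lower by at least 1.5-fold. The mutant arrays all lay above the control arrays for 285 of the changed genes and all below them for 700. Over all genes, changed or not, 6.75% separated the groups in this way, against 0.79% by chance. The count of changed genes ranged from 643 without mutant replicate 3 to 1798 without control replicate 1, and 1363 of the latter genes were among the 1503.

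Control replicate 1 stood apart from the other arrays. It lay at 80.4 on the first principal component, which held 37.4% of the variance, while the other 9 arrays lay between -21.0 and 2.69. Its correlation with the others was 0.978 to 0.982, against 0.990 to 0.996 among the other 9. In that array 219 genes differed more than 2-fold from the mean of the other controls, against 12 to 63 genes for each other array within its own group. The second component, with 20.5% of the variance, placed the mutant arrays between 8.05 and 25.4 and the other 4 controls between -33.2 and -18.2. The sex of the embryos was not determined according to the labels. Log2 values of the Y-linked gene Eif2s3y were 9.0 to 9.3 in mutant replicates 1 to 4 and in control replicates 1 and 4. They were 5.1 in mutant replicate 5, and 3.2 or 3.3 in the other controls. Eif2s3y values correlated with the group (0.514), so the groups were not balanced for this gene. An effect of sex is therefore not fully separated from that of genotype. With Eif2s3y as a covariate 1041 genes changed, of which 869 also changed without it.

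**Figure D1:**
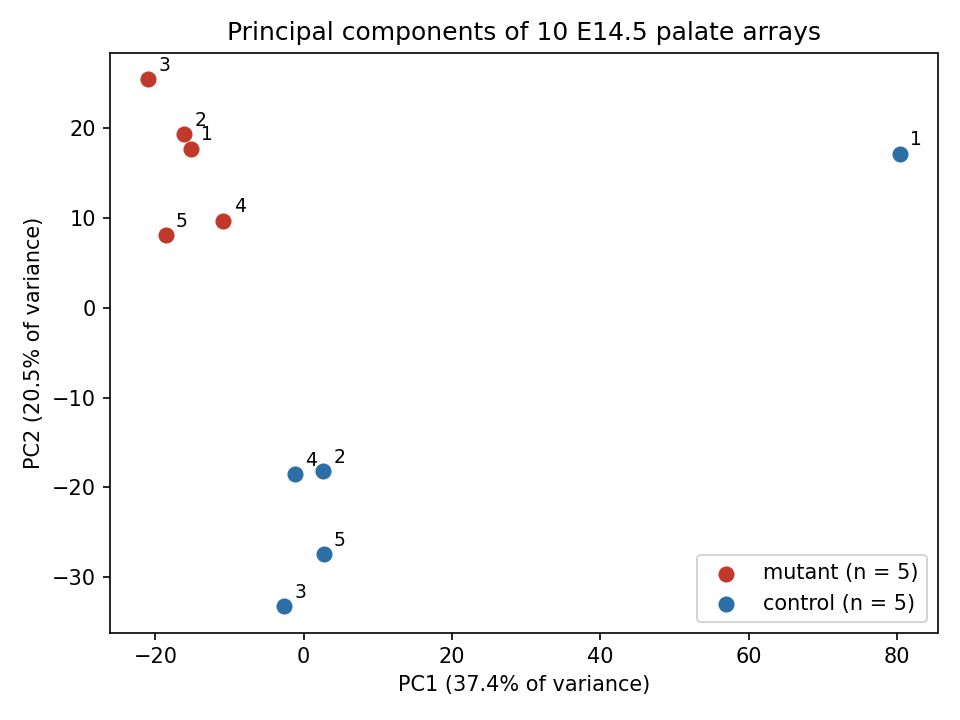
Principal components of the 10 arrays over all probe sets, with PC1 on the x axis (37.4% of variance) and PC2 on the y axis (20.5%); each point is an array, coloured by group and numbered by replicate. Control replicate 1 lies at 80.4 on PC1, and mutant and remaining control arrays part on PC2.

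Transcripts for a TGF-beta ligand and a coreceptor were higher in the mutant, while Tgfbr2 itself was not changed. Tgfb2, which encodes the ligand TGF-beta 2, was 1.92-fold higher, at 10.42 ± 0.13 in mutant and 9.48 ± 0.33 in control arrays (log2, SD, n = 5 each; adjusted p = 0.00322), and all 4 of its probe sets were higher, by 0.72 to 1.04 on the log2 scale. Tgfbr3, the coreceptor betaglycan, was 1.56-fold higher (10.20 ± 0.10 against 9.56 ± 0.32, adjusted p = 0.0156). Control replicate 1 was the lowest array for both, and without it the log2 fold changes were 0.80 and 0.50. Tgfbr2 stood at 10.74 ± 0.05 in mutant and 10.66 ± 0.11 in control arrays, a log2 fold change of 0.08 (95% confidence interval -0.06 to 0.22, adjusted p = 0.482), and its other probe sets gave -0.04 and -0.08. Where these probe sets lie relative to the floxed part is not given in the sources used here, and palate cells outside the neural crest keep the gene, so the values do not check the deletion. Tgfb1 (-0.38, interval -0.82 to 0.06), Tgfb3 (0.10, -0.04 to 0.24) and Tgfbr1 (-0.14, -0.32 to 0.04) were not called.

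**Figure D2:**
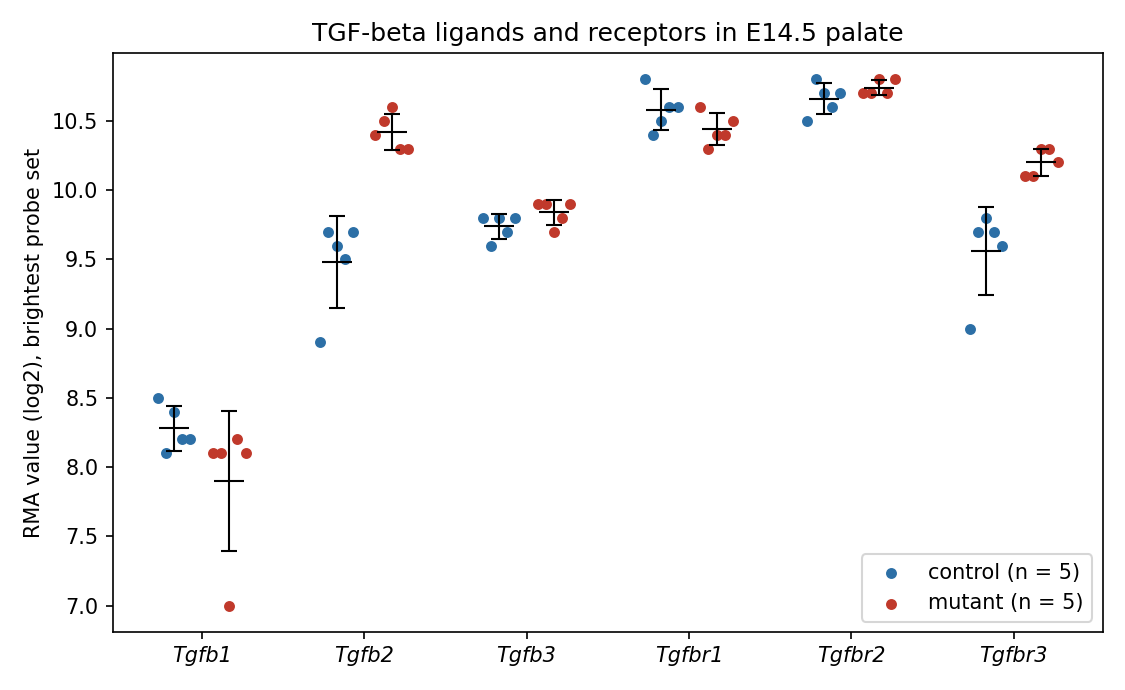
Log2 RMA values (y axis) of the brightest probe set of 6 TGF-beta ligand and receptor genes (x axis) on each array; points are arrays, and lines give the mean and SD of 5 arrays per group. Tgfb2 and Tgfbr3 separate the groups completely, and Tgfbr2 does not (10.74 against 10.66).

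Among 29 ligands, receptors and regulators of the pathway, 3 were higher and 1 lower, and 25 were not called (3 and 3 when adjusted over the list alone). Ltbp4, which encodes a latent TGF-beta binding protein, was 0.30 higher on the log2 scale (SE 0.06, adjusted p = 0.0169), and Nrros, which encodes a protein that binds latent TGF-beta 1, fell by 0.40 (SE 0.09, adjusted p = 0.0255). Among 31 genes that TGF-beta is known to induce, 6 fell and 1 rose, and 24 were not called (9 and 4 when adjusted over the list alone). Fbln5, encoding the elastic-fibre protein fibulin 5, fell by 0.92 (SE 0.12, adjusted p = 0.00191), although its other probe set moved by -0.06. Kank4 fell by 0.40 (SE 0.09, adjusted p = 0.0232), a call that was lost without mutant replicate 3 (0.0588). Ccn2, which encodes connective tissue growth factor, fell by 0.24 (SE 0.06, adjusted p = 0.0257), a call that was lost without 5 of the 10 arrays in turn. The increase was that of Cdkn1a. Neither list as a whole differed from other genes in camera (adjusted p = 0.939 and 0.614). Both passed fry's mixed test of changes in either direction (adjusted p = 1.7e-05 and 8.02e-05). On array medians the regulator list was slightly lower in mutants, at -0.006 against 0.024 (exact two-sided permutation p = 0.0238, or 0.124 adjusted over the 26 lists), and the induced genes gave p = 0.0556.

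Among changed genes whose arrays separated the groups, the largest increase was that of Sned1, an extracellular matrix gene, which was 4.11-fold higher (10.80 ± 0.12 against 8.76 ± 0.71, adjusted p = 0.00191). Control replicate 1 was the lowest array for Sned1, and the log2 fold change was 1.73 without it and 2.04 with it. The other 9 were Meig1, Hoatz, Dynlrb2, Lrrc23, Ccdc153, Wdr63, Ak7, Rsph1 and Tmem212, which were 2.30-fold to 3.63-fold higher with adjusted p between 0.00149 and 0.0159. Dynlrb2 and Wdr63 encode dynein subunits, and Rsph1 encodes a protein of the radial spoke of motile cilia. Their levels were 10.50 ± 0.14 against 9.04 ± 0.65 for Dynlrb2 and 8.48 ± 0.18 against 7.24 ± 0.66 for Rsph1.

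The 10 largest decreases under the same limit included genes of striated muscle. Tceal7 was 7.36-fold lower (4.52 ± 1.16 against 7.40 ± 0.86, adjusted p = 0.00981). Smpx, Myot and Csrp3, which encode muscle proteins, were 5.58-fold, 3.84-fold and 3.58-fold lower, Myh7, a slow myosin heavy chain, was 3.34-fold lower, and Myf5, a transcription factor that commits cells to muscle, was 3.63-fold lower (adjusted p between 0.000851 and 0.0189). Fabp4, which encodes a fatty acid binding protein, was 2.83-fold lower on its brightest probe set (4.86 ± 0.15 against 6.36 ± 0.42, adjusted p = 0.00104), with 2 of its 4 probe sets called. Vwa2, a basement membrane gene, was 2.46-fold lower, and Ctla2b and Ablim3 were each 2.30-fold lower. Mutant values of Tceal7, Smpx, Myot and Myf5 went down to 3.4, 3.6, 3.4 and 3.1, near the low end of the arrays (2.2), so the sizes and the order of these decreases are uncertain. All 20 of these genes kept their call when each array was left out in turn. Called genes with overlapping arrays included larger changes, such as Dlx1as (-3.22, adjusted p = 0.0374) and Dnaic2 (2.20, adjusted p = 0.0206).

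**Figure D3:**
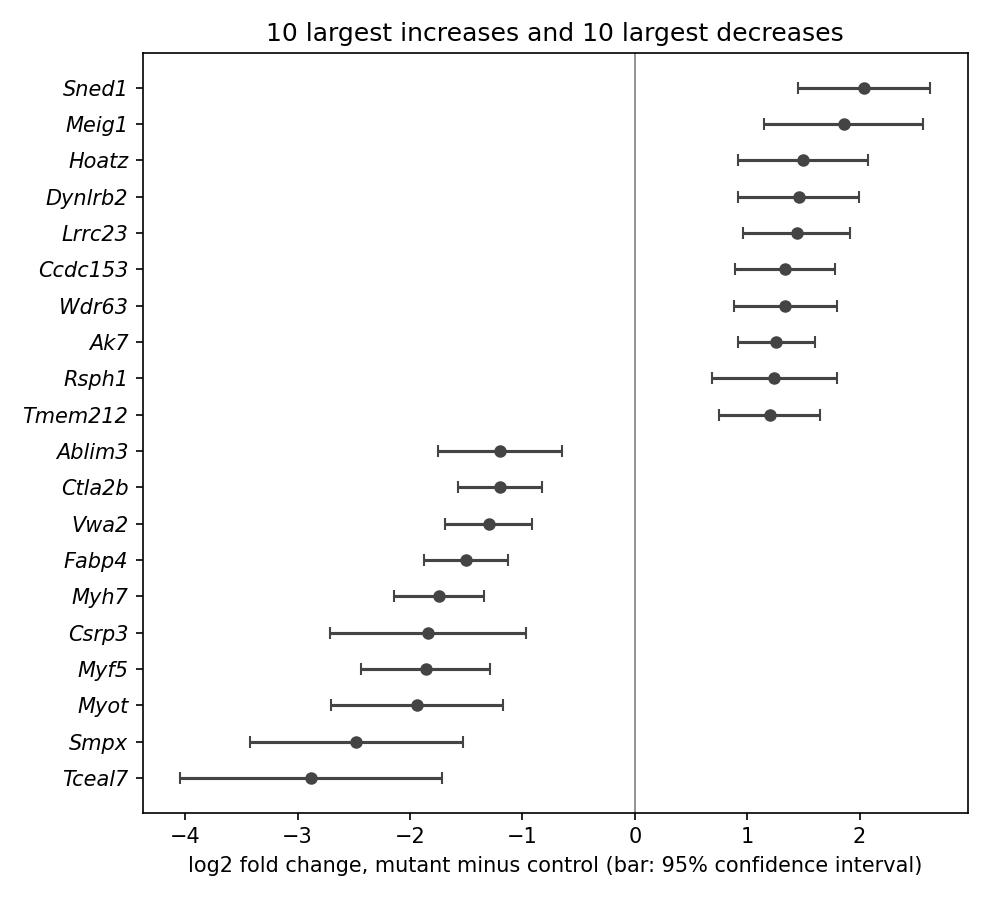
Log2 fold change, mutant minus control (x axis), of the 10 genes with the largest increase and the 10 with the largest decrease (y axis) among changed genes whose arrays separate the groups; bars are 95% confidence intervals from limma with 5 arrays per group. Sned1 leads the increases (2.04) and Tceal7 the decreases (-2.88), though the sizes and order of the decreases are uncertain where mutant values lie near the low end.

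Skeletal muscle genes fell together. Of 32 measured, 20 were lower and none higher, 12 were not called, and all 32 had a negative log2 fold change, with a median of -1.70 (31 were lower when adjusted over the list alone). Besides Myf5, the sarcomere gene Actn2 fell by 1.98 (SE 0.39, adjusted p = 0.0131) and Tnnt1, slow troponin T, fell by 1.74 (SE 0.36, adjusted p = 0.0160). The arrays overlapped, however: the list's median deviation was 0.62 in mutant replicate 4, -0.73 to -1.51 in the other mutants and 0.31 to 1.82 in controls (exact two-sided permutation p = 0.0238). The list was shifted in camera (adjusted p = 3.87e-15) but not when the correlation between its genes was estimated (adjusted p = 0.649 with an estimated correlation).

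Smooth muscle and pericyte genes moved both ways, with 2 of 18 higher, 4 lower and 12 not called (3 and 5 when adjusted over the list alone; camera adjusted p = 0.632). Array medians gave an exact two-sided permutation p of 0.0317, or 0.137 adjusted over the 26 lists, and 0.0714 without control replicate 1. Ndufa4l2 was 2.17-fold higher (adjusted p = 0.00152), and Mylk, which encodes myosin light chain kinase, was 1.65-fold higher (adjusted p = 0.00907). Myh11, the smooth muscle myosin heavy chain, was 1.43-fold lower (adjusted p = 0.00662), although its other probe set moved by 0.10. The other decreases were those of Smtn, Acta2 and Rgs5, with log2 fold changes of -0.40, -0.72 and -0.46.

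Most proliferation genes fell by a small amount. Of 39 cell cycle genes, 29 were lower, none higher and 10 not called, with a median log2 fold change of -0.40 (34 were lower when adjusted over the list alone). The mitotic genes Cenpa, Birc5 and Bub1b had log2 fold changes of -0.58, -0.56 and -0.54 (SE 0.07, 0.06 and 0.06; adjusted p = 0.00104, 0.00103 and 0.000879), although another Cenpa probe set moved by only -0.08 and 1 of its 3 was called. The list's median deviation was -0.11 to -0.30 in mutant arrays and 0.13 to 0.27 in controls, which gives the smallest exact two-sided permutation p that 5 against 5 allow, 0.00794. Among 24 cell cycle inhibitors and apoptosis genes, Cdkn1a, encoding the inhibitor p21, was 0.42 higher and Cdkn2c, another inhibitor, fell by 0.32, and each call was lost without 6 of the 10 arrays in turn (2 higher and 1 lower when adjusted over the list alone). In camera the cell cycle list was shifted (adjusted p = 6.61e-24), with adjusted p = 0.0575 with an estimated correlation, and the inhibitor list was not (0.111). The inhibitor list was shifted without control replicate 1 (0.00522), with the brighter 60% of genes (0.0344), with quantile normalization (0.0352) and with array weights (0.0142).

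Genes of cholesterol biosynthesis also fell. Of 20 measured, 12 were lower, none higher and 8 not called, with a median log2 fold change of -0.36 (18 were lower when adjusted over the list alone). Cyp51, Mvd and Mvk, which encode enzymes of the pathway, had log2 fold changes of -0.58, -0.52 and -0.40 (SE 0.10, 0.08 and 0.05; adjusted p = 0.00766, 0.00286 and 0.00160). Mutant arrays lay at -0.11 to -0.21 and controls at 0.05 to 0.33 on the list's median (exact two-sided permutation p = 0.00794). Camera gave adjusted p = 2.48e-11, and adjusted p = 0.161 with an estimated correlation.

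Hypoxia and glycolysis genes rose. Of 29 measured, 9 were higher, none lower and 20 not called, with a median log2 fold change of 0.18 (16 were higher when adjusted over the list alone). Adm, which encodes adrenomedullin, rose by 0.64 (SE 0.08, adjusted p = 0.00160), Ndrg1 by 0.56 (SE 0.08, adjusted p = 0.00233) and Bnip3, encoding a mitochondrial protein induced by low oxygen, by 0.38 (SE 0.06, adjusted p = 0.00282). Mutant arrays lay at 0.07 to 0.13 and controls at -0.04 to -0.10 (exact two-sided permutation p = 0.00794). This was the only one of the 26 lists shifted both with the preset correlation (camera adjusted p = 3.85e-10) and with an estimated one (adjusted p = 0.00204).

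**Figure D4:**
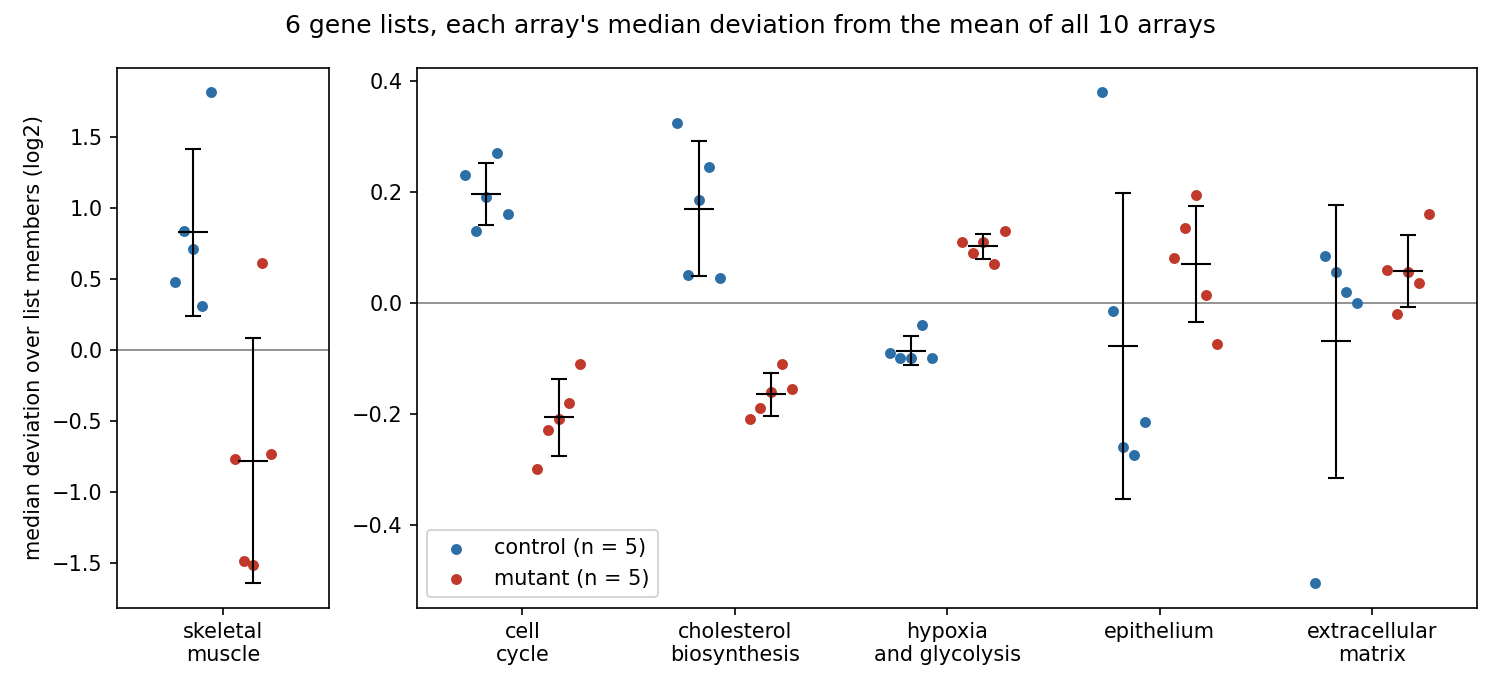
For 6 gene lists (x axis), the median over list members of the deviation from the mean of all 10 arrays (y axis, log2) on each array; points are arrays, and lines give the mean and SD of 5 arrays per group. The left panel has its own scale; cell cycle, cholesterol biosynthesis and hypoxia and glycolysis separate the groups, while mutant replicate 4 lies among the controls for skeletal muscle (0.62).

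Epithelial and extracellular matrix genes were shifted upward in camera (adjusted p = 0.0119 and 0.0492), but not with an estimated correlation (adjusted p = 0.880 for both lists), and few members were called. Of 30 epithelial genes, Krt13 and Krt4, keratins of stratified epithelium in the mouth, were higher by 1.88 and 0.92 on the log2 scale (SE 0.38 and 0.17; adjusted p = 0.0147 and 0.00907), and 28 were not called (4 higher when adjusted over the list alone). Control replicate 1 had the highest epithelial median, 0.38, against -0.28 to -0.02 in the other controls and -0.08 to 0.20 in mutants, and 10 members were higher without it. The epithelial shift was stronger without that array (camera adjusted p = 9.53e-08), and the exact two-sided permutation p on the medians went from 0.317 to 0.0238. Of 44 matrix genes, 1, Fbln5, was lower and 43 were not called (1 when adjusted over the list alone), while 30 had a positive log2 fold change, with a median of 0.14. Control replicate 1 stood at -0.51 on the matrix median, against 0.00 to 0.09 in the other controls, and camera gave adjusted p = 0.0492 with it and 0.881 without it. The matrix shift was also lost without mutant replicates 1 (0.062) and 5 (0.215), with array weights (0.499) and with rounding noise (0.0659). That of the epithelial list was lost without mutant replicate 2 (0.0515), without control replicates 3, 4 and 5 (0.0826, 0.0864 and 0.0606), and with Eif2s3y (0.572) or the muscle median (0.701) as a covariate.

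Few genes of the hard tissues were called. None of 19 osteoblast genes was called by limma, also when adjusted over the list alone, and Dlx6 had the smallest p (-0.48, adjusted p = 0.0803). The 95% confidence intervals of 7 osteoblast, 5 uncalled cartilage and 2 uncalled tooth germ genes reach a 1.5-fold change, so such changes are not excluded. Of 24 cartilage genes, Col9a2, a collagen IX chain, fell by 0.32 (adjusted p = 0.0189), Chad, encoding chondroadherin, was 0.34 higher (adjusted p = 0.0280), and 22 were not called. The Col9a2 call was lost without 1 of the 10 arrays and that of Chad without 6. Of 16 tooth germ genes, Barx1, a homeobox gene, fell by 0.34 (adjusted p = 0.0325), a call that was lost without 7 arrays, and 15 were not called. When adjusted over the list alone, 1 cartilage gene was higher and 1 lower, and 2 tooth germ genes were lower. Camera gave adjusted p = 0.317, 0.733 and 0.6 for the 3 lists, and 0.000481 for osteoblast genes with the muscle median as a covariate.

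Some transcription factors of the palate changed in opposite directions. Of 38 measured, 2 were higher, 2 lower and 34 not called (3 and 7 when adjusted over the list alone; camera adjusted p = 0.947). Tbx22, whose human counterpart is mutated in X-linked cleft palate, was 1.54-fold higher (10.14 ± 0.27 against 9.52 ± 0.21, adjusted p = 0.0183), and Foxd2 was 1.27-fold higher (adjusted p = 0.0149). Dlx2, a homeobox gene of the craniofacial neural crest, was 1.72-fold lower (7.42 ± 0.11 against 8.20 ± 0.44, adjusted p = 0.0196), and Barx1 was the other decrease. The calls of Tbx22 and Dlx2 were lost without 1 and 2 of the 10 arrays.

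Signalling pathways showed changes in named members, and no list was shifted in 1 direction by camera in the planned comparison. In the FGF list of 20, Etv5, a transcription factor induced by FGF, fell by 0.74 (SE 0.14, adjusted p = 0.0109), Fgf18, a ligand, fell by 0.44 (SE 0.08, adjusted p = 0.00810) and Spry1, a feedback inhibitor, fell by 0.32 (SE 0.08, adjusted p = 0.0300), while the receptor gene Fgfr3 rose by 0.38 (SE 0.07, adjusted p = 0.00714). In the Wnt list of 41, 4 were higher and 3 lower. Dkk2, encoding a secreted regulator of Wnt receptors, was 1.65-fold higher (9.94 ± 0.13 against 9.22 ± 0.08, adjusted p = 0.000806), Lef1, a nuclear effector of the pathway, was 1.43-fold lower (adjusted p = 0.0168) and Rspo3, which enhances Wnt signals, was 1.23-fold lower (adjusted p = 0.0135), although its other probe set moved by -0.02. The other Wnt increases were Notum (0.30), Sfrp4 (0.40) and Wnt11 (0.32), and Wnt5b fell by 0.32. In the BMP list of 31, Gdf10 fell by 0.58 (adjusted p = 0.0175), and Bmp2 and Id4 were 0.28 and 0.30 higher, calls that were lost without 7 and 9 of the 10 arrays. In the Hedgehog list of 15, Hhip was 0.44 higher (adjusted p = 0.0497), lost without 8 arrays. When adjusted over the list alone, 2 FGF genes were higher and 7 lower, 5 Wnt genes higher and 4 lower, 2 BMP genes higher and 1 lower, and no Hedgehog gene was called. Camera gave adjusted p = 0.121 for FGF, which became 0.0413 without control replicate 1, 0.0387 without control replicate 2 and 0.0254 with array weights, and 0.6, 0.927 and 0.6 for Wnt, BMP and Hedgehog. Fry's mixed test of changes in either direction gave adjusted p = 1.7e-05, 2.21e-07, 0.00409 and 0.0621 for FGF, Wnt, BMP and Hedgehog. It gave 0.00951 for the p38 MAPK pathway list. None of 20 p38 MAPK pathway genes was called by limma, and Map3k7, which encodes the kinase TAK1, had the smallest p (-0.24, adjusted p = 0.0917; camera 0.947 for the list).

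Genes of vessels, blood and immune cells changed in few members. Of 25 endothelial genes, 5 were lower and none higher. Icam2 fell by 0.52, Cldn5, a tight junction gene, fell by 0.54, Nos3, the endothelial nitric oxide synthase, fell by 0.32, Erg fell by 0.42 and Lyve1, a marker of lymphatic vessels, fell by 0.88 (adjusted p between 0.00191 and 0.0304; 5 when adjusted over the list alone). The Nos3 call was lost without 2 of the 10 arrays. The median of the list was 0.00, and camera gave adjusted p = 0.371, or 0.00755 without control replicate 1, the lowest control at -0.20, and 0.0254 with array weights. Of 15 erythroid genes, Tfrc, the transferrin receptor, fell by 0.28 (adjusted p = 0.0396), lost without 8 arrays. Of 22 macrophage genes, Pf4 fell by 0.62 (adjusted p = 0.0156) and Laptm5 was 0.28 higher (adjusted p = 0.0477), the latter lost without 9 arrays. When adjusted over the list alone, 2 erythroid genes were lower, and 3 macrophage genes were higher and 2 lower. Camera gave adjusted p = 0.204 and 0.947, and for erythroid genes 0.00735 with Eif2s3y and 0.0147 with the muscle median as a covariate.

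Of 42 lipid storage and fatty acid genes, Fabp4 and Cd36, a fatty acid transporter (-0.86, SE 0.22, adjusted p = 0.0371), were lower and 40 were not called (2 when adjusted over the list alone; camera 0.947 for the list). The Cd36 call was lost without 7 of the 10 arrays. None of 14 glia and Schwann cell genes, 19 neuronal genes or 25 immediate early and heat shock genes was called by limma over all genes or when adjusted over the list alone. The 95% confidence intervals of 13 neuronal, 4 immediate early or heat shock and 1 glial gene reach a 1.5-fold change, so the neuronal list in particular says little. The smallest p values in these 3 lists belonged to Ngfr (0.30, adjusted p = 0.0606), Prph (0.70, adjusted p = 0.114) and Ier3 (0.46, adjusted p = 0.0569). Camera gave adjusted p = 0.142, 0.733 and 0.116. Glia became shifted without control replicate 1 (0.00522), with the brighter 60% of genes (0.0463) and with array weights (0.0194). The immediate early and heat shock list became shifted without control replicate 4 (0.0176), with the brighter 60% of genes (0.0116) and with quantile normalization (0.0459). For the TGF-beta regulator list the median (-0.02) and the mean (0.0041) differed in sign, and for the BMP and lipid lists the camera direction was upward with a mean of -0.03 and -0.05. With the preset correlation 6 of 26 lists were shifted, and 9 without control replicate 1. Of 100 splits of the same arrays into 5 and 5, 85 shifted at least 6 lists, the real split included.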

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

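Of the tests of explanations in this part, those of the motile cilia genes against the epithelium list, of the muscle lineage list and of Lztfl1 were chosen after the results were seen, and the motile cilia list and the 2 other new lists compared with it were written after cilia genes had been seen among the largest increases.

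Within a group of 5 arrays, 1 array stood far from the other 4 in 21 of 204 groups of values tested. Chance marks about 1 group in 20, or 10.2, if the values are independent and not rounded. These values have steps of 0.1, and the groups share genes and arrays, so 10.2 is only a rough guide. Control replicate 1 was the distant array in 7 of the 21. It was the lowest control for Tgfb2 at 8.9 (other controls 9.5 to 9.7), for Tgfbr3 at 9.0 (9.6 to 9.8), for Sned1 at 7.5 (8.9 to 9.2) and for Fgfr3 at 9.4 (all others 9.6), and the highest for Kank4 at 8.3 (7.9 to 8.0). Its median deviation was -0.505 over the extracellular matrix list (0.00 to 0.085 in the others) and 0.135 over the cell cycle inhibitor and apoptosis list (-0.12 to -0.05).

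Mutant replicate 4 was the distant array in 4 groups, being higher than the other mutants for the muscle genes Smpx at 5.8 (3.6 to 4.2) and Actn2 at 7.8 (5.7 to 6.3) and lower for Dkk2 at 9.7 (all others 10) and Mvk at 7.7 (all others 7.8). Among mutant arrays, replicate 3 was low for Tgfb1 at 7.0 (8.1 to 8.2), replicate 1 was low for Lrrc23 at 9.3 (9.6 to 9.7), replicate 2 was low for Fabp4 at 4.6 (4.9 to 5.0) and for Bnip3 at 10.7 (all others 10.8), and replicate 5 was high for Fbln5 at 10 (9.6 to 9.7). Among control arrays, replicate 2 was low for Vwa2 at 6.3 (7.1 to 7.4) and Mvk at 8.1 (all others 8.2) and high for Adm at 6.8 (all others 6.5), and replicate 5 was high for Ablim3 at 6.7 (5.6 to 5.9). Control replicate 4 stood at -0.04 over the hypoxia and glycolysis list (-0.10 to -0.09 in the others). The gaps for Mvk and Bnip3 are a single rounding step of 0.1.

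Among 9160 probe sets without a gene symbol, which enter no comparison by gene, limma called 83 higher and 36 lower in mutant arrays after adjustment over all probe sets of the array.

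Genes of motile cilia were higher in mutant palate as a set: the median deviation of 73 genes was 0.20 to 0.56 in mutant arrays and -0.87 to 0.12 in controls. More epithelium of every kind in equal proportion, or a rise of genes of every kind of cilium, would each raise another list as much. Olfactory epithelium taken along at dissection need not do so. Some members of its list were already high in control arrays (mean log2 of Krt8 11.14 and Sox2 10.36). Others lay near the low end there (Lhx2 3.6 and Neurod1 4.02). The cilia median rose by 0.605 more than that of the epithelium list, by 0.649 more than that of olfactory and nasal epithelium (exact two-sided permutation p = 0.0159 each) and by 0.704 more than that of intraflagellar transport and basal body genes (exact p = 0.00794), and without control replicate 1 by 0.546, 0.672 and 0.752 (exact p = 0.0159, 0.0159 and 0.00794). Without the 6 genes that prompted the list the differences were 0.545, 0.589 and 0.644, with the same exact p (0.0159, 0.0159 and 0.00794). The cilia list was prompted by these same arrays, so its rise over another list was partly built in. The exact p-values of these differences are therefore no independent support. Intraflagellar transport and basal body genes themselves rose by 0.048 on array medians (exact two-sided permutation p = 0.214). In these arrays the epithelium and intraflagellar transport lists thus did not rise as much as the cilia list, and no cause is excluded by this. The comparison with the olfactory list cannot decide, as an equal rise need not follow. That list rose too (exact two-sided permutation p = 0.0476, or 0.00794 without control replicate 1). A larger share of ciliated nasal lining in the mutant pieces and a larger number of ciliated cells in the mutant tissue both stay open, so a change in the tissue itself is only a hypothesis.

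Skeletal muscle genes were lower in 4 of the 5 mutant arrays, with mutant replicate 4 among the controls. Across 27 muscle genes with a mean log2 value above 6, the size of the group difference followed the loading on the first within-group component (Spearman's rho = 0.958, across genes, which are not independent replicates), and that component held 88.8% of the variance of these genes within groups. A different amount of muscle tissue in the pieces, varying among arrays of the same group too, would give such a rho. Any coordinated fall of these genes would give it as well, so the rho does not tell these causes apart. A fall of contractile genes alone in an unchanged number of muscle cells is argued against as the whole cause by the muscle lineage list, whose median changed by -0.556 (exact two-sided permutation p = 0.0159), but 6 of its 13 members are also in the skeletal muscle list: the other 7 changed by only -0.24 (exact p = 0.00794, or 0.0159 without control replicate 1), against -1.78 for contractile genes, Pax3 among them was 0.58 higher, and camera gave p = 0.0805 for all 13 with an estimated correlation. Whether the embryos had less palatal muscle, its cells had less of both contractile and lineage transcripts, or the dissection took less of it stays open.

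One probe set of Lztfl1, a gene chosen after its values were seen, had the strongest change among its 5: 3.30 ± 0.12 in mutant and 6.66 ± 0.23 in control arrays (log2, SD, n = 5 each), a difference of -3.36 (limma adjusted p = 1.1e-07) whose size is uncertain, as the mutant values lie near the low end of the arrays (2.2). Lower expression of the whole gene is argued against by its brightest probe set, which changed by -0.02, and the other 3 changed by -0.48, -0.32 and -0.10. Among the 20 measured neighbours of Lztfl1, 4 had a changed probe set (Clec3b 0.32, Lars2 -0.82, Limd1 -0.58 and 2010315B03Rik -0.98), which 3.19% of 17735 such windows reached, the median window holding 1. A chromosome segment that differs between the groups, with sequence variants under the probes, may be a source. Lztfl1 and its window were chosen after the values were seen, and no variant or probe sequence was examined. The window is therefore no independent support. Tgfbr2 lies on the same chromosome, 79 measured genes away, with 2 changed genes among its own neighbours. By the genotype labels both groups carry the floxed alleles, so a segment carried with these would be shared, although titles call the controls wildtype. Altered transcript ends of Lztfl1 in the mutant were not tested.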

How the results depend on the processing

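The Eif2s3y covariate, the rounding noise and the muscle covariate were chosen after the data were seen. The count of 1503 changed genes lay between 1041 (Eif2s3y covariate, 869 shared genes) and 2240 (array weights, 1494 shared) under the other settings apart from those given next, and median centring moved the share of lower genes from 64.9% to 70.5%. With the brighter 60% of genes, 176 genes changed at least 1.5-fold, fewer genes being tested, and 74.7% of the changed genes were lower. With array weights 907 genes were higher. Against a 1.2-fold change limma's treat called 48 genes, all among the 1503, since small changes no longer count. Adding the muscle median, which correlated with the group (-0.773), left 3 changed genes, all 3 at least 1.5-fold, 1 higher and 2 lower, and the list test of skeletal muscle reversed in direction (adjusted p = 0.558). Over the 1483 changed genes outside the muscle list the covariate kept the log2 fold change (median ratio 1.01) and widened its error (median ratio of SE 1.63). For the 20 in the list the median size of the log2 fold change went from 1.96 to 0.112, as the covariate is the median of these genes. With the replicate number as a block (replicate block), 532 genes changed (511 of them shared), 163 at least 1.5-fold, 167 higher and 365 lower; the numbers do not pair the samples, with correlations of -0.10 to 0.11 and 0 of 5 mutant arrays closest to their own number, and the cause was not tested. Under the block the FGF signalling list became shifted (adjusted p = 0.0475) and no list lost its shift. With an estimated correlation 1 list was shifted in place of 6, as genes of a list vary together. For Tgfbr2 the mean of all probe sets gave -0.013 in place of 0.08, neither called (adjusted p = 0.91; 0.168 to 0.91 over all settings).

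Leaving out each array in turn gave 643 to 1798 changed genes, 180 to 357 at least 1.5-fold, 186 to 691 higher, 457 to 1107 lower, 5 to 9 shifted lists and a Tgfbr2 log2 fold change of 0.04 to 0.12. The count of changed genes moved by more than 1.5 times without mutant replicates 1 (846), 2 (861), 3 (643) and 5 (887) and control replicates 3 (793) and 5 (972), with fewer samples in the fit. Of 67 called genes named by the rule, 51 kept the call without each array and 16 lost it at least once, and no called gene changed direction. Of all 76, 47 kept call and direction under every setting that tested them but the block and the muscle covariate, which took the call of 25 and 67, and 4 kept them under every setting; 14 of 26 lists kept theirs under every setting. The number of arrays limits small changes, and 18% of simulated 1.2-fold changes were recovered, against 80% of 1.5-fold ones. The simulation called 161 genes in place of 1503, which makes the adjusted p harder to pass. Recovery in the real comparison may therefore be higher.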

Other observations

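The motile cilia list, the lists compared with it, the muscle lineage list and the neutrophil list in this part were chosen after the data were seen, as were all genes named here; the splits of the arrays were planned. Genes of motile cilia, the beating cilia of airway and nasal lining, were higher in mutant palate. Of 73 measured, 48 were higher and none lower in limma over all genes, with a median log2 fold change of 0.86, and 53 were higher without control replicate 1. Foxj1, the transcription factor that drives formation of motile cilia, was 0.88 higher (8.82 ± 0.30 against 7.94 ± 0.50, adjusted p = 0.0323), Dnaic2, a subunit of the outer dynein arm, was 2.20 higher (adjusted p = 0.0206) and Tekt1, a protein of ciliary microtubules, 0.94 higher (adjusted p = 0.0333). The list was built after Dynlrb2, Rsph1 and others had been seen among the 10 largest increases of genes whose arrays separate the groups. Without the 6 of its members among those, 42 of 67 were higher, none lower, with a median of 0.82. All mutant arrays lay above all control arrays on the median of these 67 (exact two-sided permutation p = 0.00794, the smallest possible). Camera gave p = 5.76e-30, or p = 0.0368 with an estimated correlation, and none of these p-values is adjusted over lists. The 73 genes varied together (estimated correlation 0.526), far above the preset 0.01. The 67 are therefore no independent check of a list prompted by these same arrays. Of 33 intraflagellar transport and basal body genes, which cilia of every kind use, Ift22 was higher (0.46) and 32 were not called, with a median of 0.04.

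Of 22 olfactory and nasal epithelium genes, none was higher, Pax6 fell by 0.38 and 21 were not called, with a median of 0.14. The list was nevertheless higher in mutant arrays on balance: camera gave p = 0.012, or 0.0566 with an estimated correlation, and the exact two-sided permutation p was 0.0476. Without control replicate 1 the exact p was 0.00794, 2 members were higher and none lower, and the Pax6 call was lost. Of 13 muscle lineage genes, Myf5, Cdh15, Msc, Megf10 and Myod1 were lower (-1.86, -0.74, -0.82, -0.52 and -0.92) and Pax3, which marks muscle precursors and early neural crest, was higher (0.58, adjusted p = 0.0131).

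Sex-linked genes differed between arrays of the same group. Xist, transcribed from the inactive X chromosome, stood at 12.7 or 12.8 in mutant replicate 5 and control replicates 2, 3 and 5, and at 6.3 to 6.7 in mutant replicates 1 to 4 and control replicate 1. Control replicate 4 had both Xist at 10.5 and the Y-linked genes Eif2s3y at 9.0, Kdm5d at 8.0 and Uty at 7.7. Eif2s3y alone therefore does not tell the sex of this sample, and the labels do not say whether it held more than 1 embryo. Mutant replicate 5 had Eif2s3y at 5.1 against 3.2 or 3.3 in control replicates 2, 3 and 5.

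Of 16 neutrophil genes, 7 were highest in control replicate 1 and 9 were not. The former include S100a8 (8.0, against at most 6.8 in the other arrays), S100a9 (7.8 against 6.1), Ngp (6.6 against 5.5) and Pglyrp1 (8.0 against 7.4). None of the 16 was called by limma between the groups.

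Of 100 of the 126 distinct splits of the 10 arrays into 5 and 5, only the real one, 1 split, gave as many changed genes (1503, highest other 2). Likewise 1 split gave as many genes changed at least 1.5-fold (292, highest other 2), 1 split as many higher genes (528, highest other 2) and 1 split as many lower genes (975, highest other 2). These values argue against chance for these 4 counts, which come from 1 fit and are not separate tests. Such splits cannot tell genotype from anything else that differs between the groups, such as sex. For the number of shifted lists, 85 of the 100 splits gave at least 6, with 16 the highest and 8 the median of the others. Chance is therefore not excluded for the number of shifted lists, and these splits point to genes of a list that vary together from array to array.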
